A study of Mus musculus with 7 samples.

How the data were processed

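The deposited count values are UMI counts per gene and cell barcode that the authors made with Cell Ranger from 10x Genomics 3′ v2 libraries against GRCm38, before deposition. The authors also name Seurat; their versions, cell filters and clustering settings are not given in the sources used here. Raw reads were not used here. Labels give 5 mice per group, a goal of 5000 cells and bead enrichment for CD45 or CD4, and do not say which mice are in which library. The CD4 libraries held Xist and the CD45 libraries Y-linked transcripts (110.8 to 127.2 CPM), so sort, sex and processing batch cannot be told apart, and the sort was a term of every model over both sorts. The files of the sorts list different numbers of genes, and the 27998 genes in all libraries were used.

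Barcodes with fewer than 200 genes or more than 10% mitochondrial UMIs were removed, as were those most like simulated doublets, at 0.8% per 1000 barcodes. Counts were scaled to 10000 UMIs per cell and logged. The 2000 most variable genes, 30 principal components and 15 neighbours gave Leiden clusters at resolution 1.0 for each sort, and T lineage clusters were clustered again. Clusters were named by marker scores, and Tregs by a score of at least 0.5 with 3 Treg markers among the top 10 genes. Barcodes with T cell (at least 5 per 10000 UMIs and 2 UMIs) and myeloid (at least 150 per 10000) transcripts together were set apart as mixed. The rule for mixed barcodes, the naming of T cells and Tregs and the leaving out of genes that follow the cell cycle were set after the cell clusters were seen and before any test between genotypes; a Treg score of at least 1.0 was planned first, and the rule used keeps 1 further cluster of 729 cells of the CD4 libraries with a score of 0.997.

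Counts were summed per library and class with at least 20 cells. edgeR (quasi-likelihood, TMM, filterByExpr) tested genotype with two-sided tests, and adjusted p values are Benjamini-Hochberg at 0.05. DESeq2 was the other tool. Gene lists were tested with camera of limma (two-sided, preset correlation 0.01), again with an estimated correlation, and with fry; adjusted p values of lists are from camera unless stated. Treg shares were compared with two-sided exact permutations within sort, and intervals of shares are Clopper-Pearson. CPM of a gene in an edgeR result are per 1e6 UMIs of the tested genes of that class; CPM of Lag3, Foxp3 and other genes named in advance, and of Tpm3, use all UMIs of the class or library. A group with 0 UMIs was given a floor of 3 UMIs for a fold.

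Changes of 1.5, 2 or 4-fold were put into the counts of drawn genes to test the procedure. In Tregs over both sorts 110 calls held 15 false ones, and 46.3% of genes changed 2-fold and 89.4% of those changed 4-fold were found. In Tconv over both sorts 132 calls held 21 false ones, with 56.7% found at 2-fold. In Tregs of the CD45 libraries 34.8% were found at 4-fold, and in CD45 monocytes or macrophages 26 of 116 calls were false, so false calls exceed 5%. The 1 shifted list was called and 0 of 30 random lists were. Counts were drawn for each gene apart, so this does not test false calls in lists whose genes vary together. In monocytes or macrophages the type I interferon list had an estimated correlation of 0.327. Python 3.11.15, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

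For class shares, removing mixed barcodes before clustering was first expressed over the remaining cells, where most shares move because the denominator is smaller, then left out after those values were seen, and then restored over the same cells as the other settings.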

Results

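Single-cell RNA was measured in cells from the central nervous system of C57BL/6 mice at the peak of experimental autoimmune encephalomyelitis, an inflammatory disease that follows immunization with a myelin peptide. LAG3 is an inhibitory receptor that binds MHC class II, and the series sets mice without it (Lag3KO) beside wild-type mice (WT), with regulatory T cells (Tregs) as its subject. The 7 libraries, in 4 groups, came from cells enriched for CD4 (WT_CD4 and Lag3KO_CD4, n = 2 each) or for CD45 (WT_CD45, n = 2, and Lag3KO_CD45, n = 1). A library held 4585251 to 18940186 UMIs in 1428 to 2517 barcodes. Median depth was 2086.5 to 2599.5 UMIs per barcode in the CD4 libraries and 5683 to 6407 in the CD45 libraries. Unless stated otherwise, differences are Lag3KO minus WT on the log2 scale with their standard error (SE), from 3 Lag3KO and 4 WT libraries with the sort as a term.

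Lag3 transcripts were almost absent from the 3 Lag3KO libraries and also from 1 library labelled WT. Over all barcodes, WT_CD4 1 held 289 Lag3 UMIs (50.0 UMIs per 1e6, CPM), WT_CD4 2 held 107 (23.3 CPM) and WT_CD45 1 held 304 (16.4 CPM). Lag3KO_CD4 1, Lag3KO_CD4 2 and Lag3KO_CD45 1 held 1, 0 and 2 Lag3 UMIs. The library labelled WT_CD45 2 held 4 (0.249 CPM), where the rate of WT_CD45 1 would have given 263.4, so its Lag3 level contradicts its label. Every comparison below keeps the label, and directions drawn from the CD45 libraries rest on it. The sources used here give neither the deleted exons nor the Cre line, and a 3′ tag outside the deleted part checks nothing, so these counts measure Lag3 3′ tags and not the deletion itself.

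In the CD4 libraries the highest Lag3 levels were in plasmacytoid dendritic cells and microglia, the resident macrophages of the brain. WT microglia held 92 Lag3 UMIs (323.5 CPM) and Lag3KO microglia held 1 (1.44 CPM), a Lag3KO to WT ratio of 0.00444 (95% interval 0.000111 to 0.0253). WT plasmacytoid dendritic cells held 21 Lag3 UMIs (408.8 CPM) and those of the Lag3KO libraries 0, at least 5.82-fold lower with a floor of 3 UMIs over the group. Conventional CD4 T cells (Tconv) held 169 Lag3 UMIs (62.8 CPM) in WT_CD4 1, 17 (8.16 CPM) in WT_CD4 2 and 0 in Lag3KO, so their pooled WT level of 39.0 CPM rests on WT_CD4 1. Tregs held 28 Lag3 UMIs (10.2 CPM; 16 UMIs in WT_CD4 1 and 12, or 9.36 CPM, in WT_CD4 2) in WT and 0 in Lag3KO, at least 7.13-fold lower. In WT_CD45 1, 62.3% of plasmacytoid dendritic cells (38 of 61, 95% Clopper-Pearson interval 49.0 to 74.4, median depth 5316 UMIs) and 17.9% of Tconv (24 of 134, 11.8 to 25.5, median depth 3218.5) had a Lag3 UMI. For background, gamma delta T cells of that library had 0 of 33 (median depth 3253, upper limit 10.6%) and monocytes or macrophages 1.40% (median depth 6061.5). In the library labelled WT_CD45 2 the share was 1 of 61 plasmacytoid dendritic cells and 0 of 209 Tconv.

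**Figure D1:**
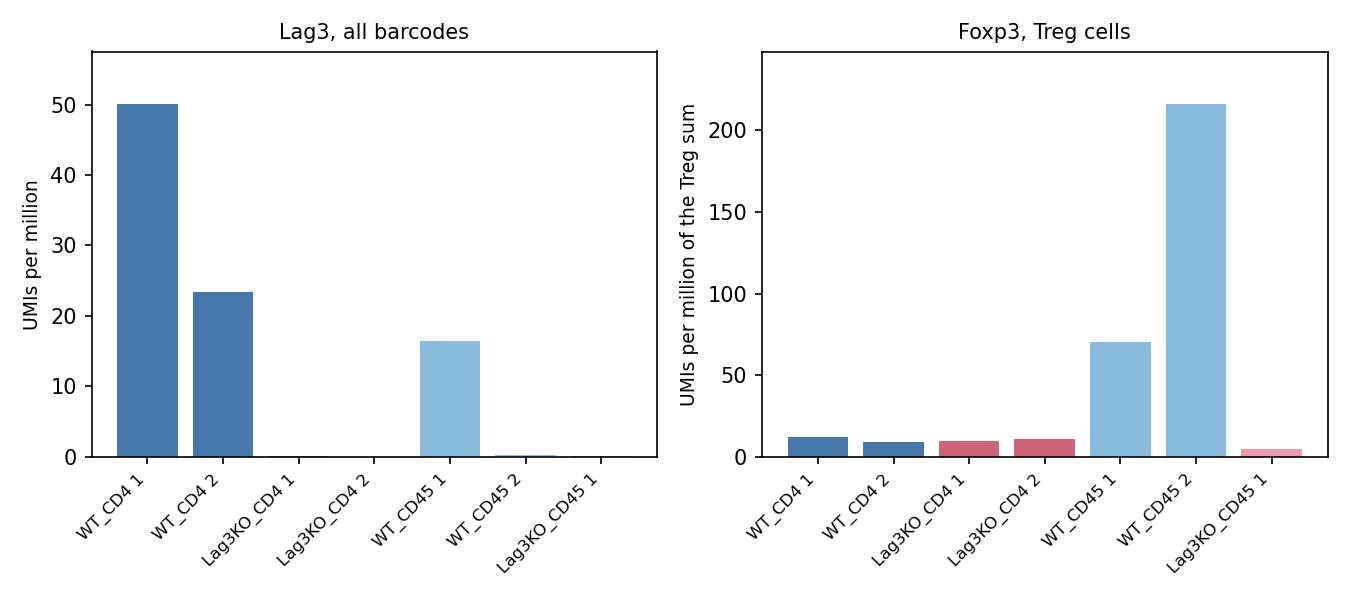
Lag3 CPM over all barcodes (left) and Foxp3 CPM of the Treg sum (right), 1 bar per library, coloured by group. Lag3 lay at 16.4 to 50.0 in WT_CD4 1, WT_CD4 2 and WT_CD45 1 and at 0.249 or less in the others, the library labelled WT_CD45 2 included; Foxp3 was highest in the library labelled WT_CD45 2, at 215.8.

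Tregs were named from several markers because Foxp3, their lineage transcription factor, gave few 3′ tags in 5 of the 7 libraries. The Foxp3 CPM of Tregs was 12.4 and 9.36 in WT_CD4 1 and 2, 9.78 and 10.9 in Lag3KO_CD4 1 and 2, and 4.64 (1 UMI) in Lag3KO_CD45 1. It was 70.6 in WT_CD45 1 and 215.8 in the library labelled WT_CD45 2. At least 1 Foxp3 UMI was found in 62.1% of Tregs of that library (41 of 66, median depth 3668 UMIs) and in 2.56% of those of Lag3KO_CD45 1 (1 of 39, median depth 4510). For background in the library labelled WT_CD45 2, where the gene should be rare outside Tregs, Tconv showed 0.478% (median depth 3232), NK cells 2.33%, cDC1 3.77%, plasmacytoid dendritic cells 4.92% and B cells 5.56% (3 of 54). Over 15 other Treg markers, the median ratio of the 5 libraries with few Foxp3 tags to the WT_CD45 libraries was 0.867, with a range from 0.470 (Itgae) to 2.25 (Socs2). Of these 15, 9 also served to name the class. The other 6 were higher in Tregs than in Tconv of the 5 libraries pooled, by 1.65-fold (Entpd1) to 17.4-fold (Lrrc32).

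Tregs made up a smaller share of CD4 T cells in the Lag3KO than in the WT libraries of the CD4 sort, and not in those of the CD45 sort. The share was 30.5% (95% Clopper-Pearson interval 28.3 to 32.9) and 31.1% (28.4 to 33.9) in WT_CD4 1 and 2, against 21.6% (19.1 to 24.3) and 27.4% (25.1 to 29.8) in Lag3KO_CD4 1 and 2. The group means were 30.8% ± 0.410 (SD, n = 2) and 24.5% ± 4.10 (SD, n = 2). In the CD45 sort the share was 16.8% (11.3 to 23.5) in WT_CD45 1, 24.0% (19.1 to 29.5) in the library labelled WT_CD45 2 and 23.4% (17.2 to 30.5) in Lag3KO_CD45 1. These shares leave out the mixed barcodes, of which 41, 63 and 8 held a Foxp3 UMI, in the same order. Among the Tregs 6, 41 and 1 did. Over both sorts the difference was -2.61 percentage points, with a two-sided exact permutation p = 0.556 over 18 arrangements within sort, of which 0.0556 is the smallest possible. Within the CD4 libraries alone it was -6.33 points and within the CD45 libraries alone 2.97 points, with only 6 and 3 arrangements to compare. Without Lag3KO_CD4 1 it was -0.233 points, without WT_CD4 2 it was -1.54, and without Lag3KO_CD45 1 or WT_CD45 1 it was -6.33 or -4.44. With a Treg score of at least 1.0 it was -1.40, and the shares were 18.2% and 13.5% in WT_CD4 against 12.6% and 10.5% in Lag3KO_CD4. With Tregs taken as CD4 T cells that hold a Foxp3 UMI it was -3.47 (exact p = 0.444), and the shares overlapped in the CD4 sort (1.14% and 1.06% in WT_CD4, 1.00% and 1.10% in Lag3KO_CD4).

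**Figure D2:**
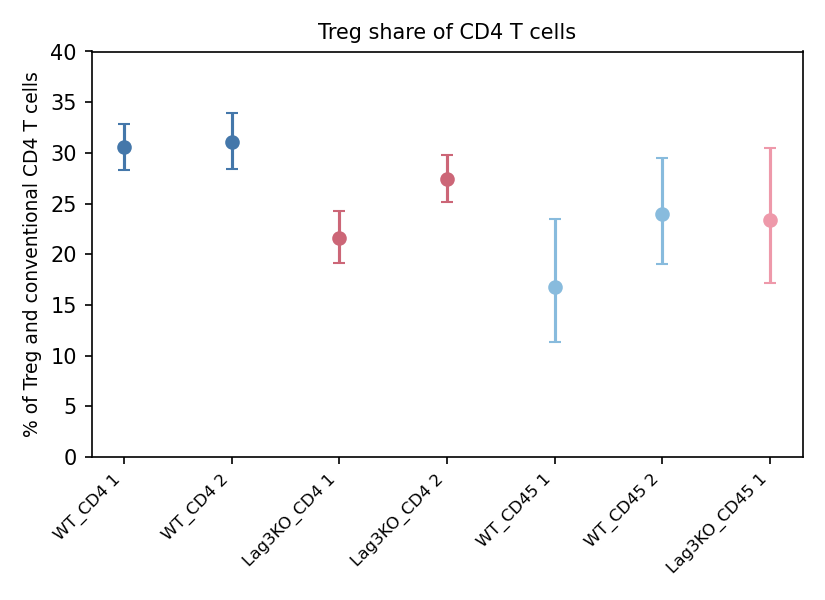
Treg share (%) of Treg and conventional CD4 T cells in each of the 7 libraries, coloured by group. Points are shares and bars 95% Clopper-Pearson intervals; the 2 Lag3KO_CD4 libraries lie at 21.6 and 27.4, below the 2 WT_CD4 libraries at 30.5 and 31.1.

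In Tregs, 8 of 7663 tested genes differed by genotype over both sorts (edgeR, adjusted p under 0.05), 5 higher and 3 lower in Lag3KO. Lag3 itself was tested and did not pass (-6.04 ± 1.46 SE, edgeR adjusted p = 0.141). Tregs of the library labelled WT_CD45 2 held 0 Lag3 UMIs. Higher were Emp1, an epithelial membrane protein (1.47 ± 0.23 SE, adjusted p = 0.00236), Sv2c, a synaptic vesicle glycoprotein (1.40 ± 0.23, adjusted p = 0.00309), Serpinb6b, a serine protease inhibitor (1.27 ± 0.22, adjusted p = 0.0192), and C1qa, a chain of complement C1q that macrophages and microglia make (1.47 ± 0.30, adjusted p = 0.0230). Lower were H2-Q7, a non-classical MHC class I gene (-0.73 ± 0.13, adjusted p = 0.00309), Wdr89 (-0.73 ± 0.14, adjusted p = 0.0117) and Clec2i, a C-type lectin (-1.51 ± 0.31, adjusted p = 0.0192). For 6 of these 7 every Lag3KO library lay beyond all WT libraries of its sort; for Emp1 this held in 2 of 3. The eighth, Lgals3, which encodes galectin-3 (0.84 ± 0.17, adjusted p = 0.0192), stands outside the naming rule because its fitted sign differed between the sorts (1.04 in CD4, -0.02 in CD45).

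Sv2c in Tregs stood at 26.3 and 20.3 CPM in the WT_CD4 libraries, 64.1 and 37.2 in Lag3KO_CD4, 60.7 in WT_CD45 1, 70.3 in the library labelled WT_CD45 2 and 277.3 in Lag3KO_CD45 1. H2-Q7 stood at 688.4 and 835.7 in WT_CD4, 362.1 and 455.7 in Lag3KO_CD4, 890.1 in WT_CD45 1, 780.0 in the library labelled WT_CD45 2 and 616.8 in Lag3KO_CD45 1. C1qa was low in the CD4 libraries (WT_CD4 1.79 ± 0.326 SD and Lag3KO_CD4 12.5 ± 0.0840 SD CPM, n = 2 each) and stood at 107.5 ± 18.5 (SD, n = 2) in WT_CD45 and 234.3 in Lag3KO_CD45 1. Clec2i in the Lag3KO_CD45 Tregs had 0 UMIs against 8 in WT_CD45, at least 1.23-fold lower. Emp1 (135362545 to 135383173) and Clec2i (128887588 to 128898167) lie on chromosome 6, as Lag3 does. Leaving out WT_CD4 2 ended all 8 calls, while leaving out WT_CD45 1 or the library labelled WT_CD45 2 gave 13 or 14. The stricter Treg score, which was planned first, gave 2 genes, DESeq2 5 and no count filter 20.

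**Figure D3:**
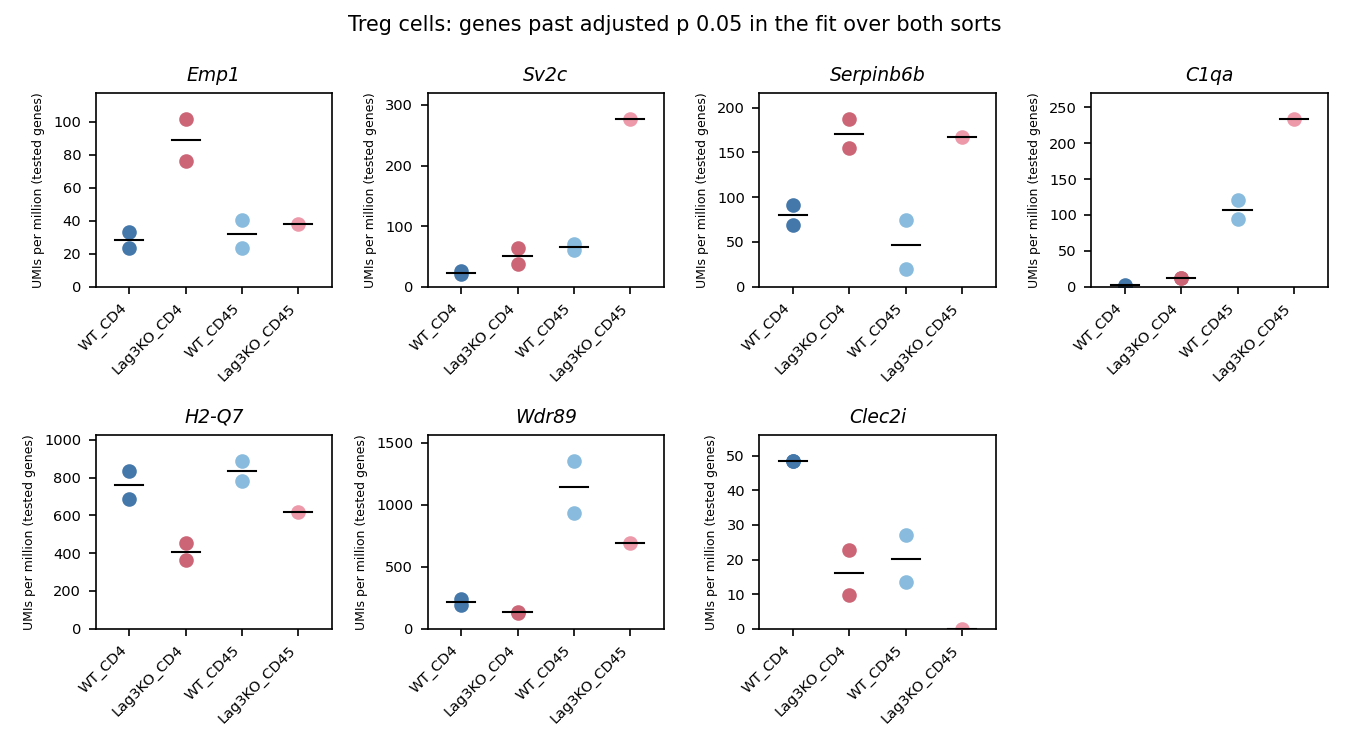
CPM among the tested genes in Tregs for Emp1, Sv2c, Serpinb6b, C1qa, H2-Q7, Wdr89 and Clec2i, 1 point per library, with the group mean as a line (n = 2, 2, 2 and 1 from left to right). Sv2c in Lag3KO_CD45 1 stands at 277.3 and Clec2i there at 0; the WT_CD45 group includes the library labelled WT_CD45 2.

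Within the CD4 libraries, 9 Treg genes differed (edgeR, 6 higher and 3 lower), and Tpm3, an actin-binding tropomyosin, had the smallest p. Tpm3 was lower by 2.24 ± 0.17 (SE; log2 difference -2.24, adjusted p = 2.28e-10). H2-Aa, an MHC class II chain (2.37 ± 0.42, adjusted p = 0.00345), and Lgals3 (1.04 ± 0.17, adjusted p = 0.00107) were higher. The Tpm3 change mirrored that of its near copy Tpm3-rs7, which rose from 4.80 to 267.5 CPM in these Tregs while Tpm3 went from 335.5 to 69.6. Their sum was 340.2 in WT and 337 in Lag3KO. In the CD45 libraries edgeR called 1 Treg gene, Sv2c (2.05 ± 0.36, adjusted p = 0.0234), and DESeq2 0 (179 at an unadjusted p under 0.05). The Lag3KO side there is 1 library with 39 Tregs, so the spread comes from the other groups. The genotype effects of the sorts differed for Tpm3 (CD4 minus CD45 -2.27 ± 0.30, adjusted p = 0.000135) and H2-Aa (3.55 ± 0.55, adjusted p = 0.00139). Without WT_CD4 1 or 2 the CD4 count was 3 or 4 and without Lag3KO_CD4 1 it was 17. With haemoglobin, which only WT_CD4 2 and Lag3KO_CD4 2 of the CD4 libraries hold, as a block, it was 22 and the CD45 count 6. Without Lag3KO_CD4 1 the CD45 count was 4, without WT_CD45 1 it was 6 and without the library labelled WT_CD45 2 it was 5, or 2 without WT_CD4 1 or 2; the difference between sorts then gave 7 genes without the library labelled WT_CD45 2, 4 without Lag3KO_CD4 2 and 3 without WT_CD4 2 or WT_CD45 1.

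By gene list, the Tregs of the Lag3KO libraries carried more RNA of a myeloid marker list. That list is a check for RNA of other cells, and no list of T cell function was called. Of 21 measured myeloid markers 15 had a positive difference (camera adjusted p = 0.00427), 2 passed over all genes and 5 passed adjusted over the list alone, among them C1qb (1.01 ± 0.25), Ifitm3 (0.56 ± 0.17) and the named C1qa and Lgals3. That call was lost with an estimated correlation (adjusted p = 0.511 with an estimated correlation). It was also lost without WT_CD4 1 or Lag3KO_CD4 2, where no list was called; without Lag3KO_CD4 1 or the library labelled WT_CD45 2 there were 2 called lists and without Lag3KO_CD45 1 there were 6. Of 17 Treg identity genes, 7 were positive and 10 negative, and adjusted over the list alone Socs2 (0.71 ± 0.16), an inhibitor of cytokine signalling, was higher and Ikzf2 (-0.39 ± 0.12), which encodes the Treg factor Helios, lower. Of 9 cytotoxic granule genes, 3 were higher adjusted over the list alone and 0 over all genes: Gzmb (0.80 ± 0.18), Gzmk (1.04 ± 0.31) and Ccl5 (1.29 ± 0.31), a granule-stored chemokine. The 3 markers of NK and CD8 T cells had positive differences as well (median 0.73, camera adjusted p = 0.145), with 0 past the threshold over all genes or the list alone. Gzmb was also past the threshold among 18 effector and tissue Treg genes (median -0.09, mean 0.01, camera direction down, adjusted p = 0.945), Socs2 and Gzmb among 17 IL-2 and STAT5 genes, and Cd96 (-0.81 ± 0.23) among 8 co-inhibitory receptors. Of 30 type I interferon genes 28 were positive (median 0.35, camera adjusted p = 0.0972), with 0 past the threshold adjusted over the list alone or over all genes in edgeR. The Th1 list (9 of 14 positive, camera adjusted p = 0.0972) and the Th17 list (8 of 10 negative, camera adjusted p = 0.848) were not called.

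No Treg effector or growth gene named in advance differed over both sorts in Tregs. Il2ra differed by 0.14 ± 0.29 (SE), Ctla4 by 0.14 ± 0.13, Il10 by 0.21 ± 0.53, Ifng by -0.43 ± 1.30, Il17a by -0.74 ± 0.84, Csf2 by -0.00 ± 0.57, Myc by 0.22 ± 0.26 and Foxp3 by -1.34 ± 0.95 (edgeR adjusted p = 1.00 for each). The Foxp3 value rests on the 2 WT_CD45 libraries. In Tconv, Il2ra differed by 0.46 ± 0.25, Ctla4 by 0.65 ± 0.19, Ifng by -0.21 ± 0.71, Il17a by -0.29 ± 0.83, Csf2 by 0.51 ± 0.77 and Myc by -0.30 ± 0.23 (edgeR adjusted p = 1.00 for each). Tconv held too few Foxp3 and Il10 UMIs to be tested, at 0.186 and 1.78 CPM in WT_CD4 and 1.03 and 2.54 in Lag3KO_CD4.

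In Tconv no gene passed over both sorts with the sort as the only other term: edgeR called 0 of 9699, with 297 at an unadjusted p under 0.05, and DESeq2 called 1. With haemoglobin as a block edgeR called 11, 3 higher and 8 lower, and 10 within the CD4 libraries. Within the CD4 libraries 4 genes differed in edgeR, 1 higher and 3 lower: Tpm3 (-2.51 ± 0.22 SE, adjusted p = 7.3e-04), Myo1f, a myosin (-1.49 ± 0.22, adjusted p = 0.0190), and Clec2i (-2.24 ± 0.35, adjusted p = 0.0447) were lower. In the CD45 libraries edgeR and DESeq2 each called 0, with 520 (edgeR) and 137 (DESeq2) at an unadjusted p under 0.05, but edgeR called 28 with only the libraries of this sort and 12 with no filter. The difference between sorts gave 0 in edgeR (423 at an unadjusted p under 0.05) and 1 in DESeq2. Without Lag3KO_CD4 2 the count over both sorts was 8, without Lag3KO_CD45 1 it was 3 and without Lag3KO_CD4 1 or WT_CD4 1 it was 1. The CD45 count was 1 without WT_CD45 1, and the difference between sorts gave 2 genes without Lag3KO_CD4 1 or the library labelled WT_CD45 2. The CD4 count was 8 or 9 without Lag3KO_CD4 1 or 2, and 2 without either WT_CD4 library.

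In Tconv 7 lists were called by camera with its preset correlation, and none with an estimated one (adjusted p = 0.981 with an estimated correlation for each of the 7); 0 members of these lists passed over all genes in edgeR. Camera called higher the G2 and M phase list (32 of 42 positive, median 0.28, camera adjusted p = 0.00984), the nuclear oxidative phosphorylation list (58 of 76 positive, median 0.05, 0.0264) and the effector and tissue Treg list (13 of 18 positive, median 0.22, 0.0293). It also called higher the IL-2 and STAT5 list (12 of 16 positive, median 0.28, 0.0293) and the co-stimulatory receptor list (8 of 9 positive, median 0.22, 0.0293). It called lower the heat shock list (14 of 20 negative, median -0.22, 0.0264) and the neutrophil markers (6 of 6 negative, median -0.94, 0.0211). Tnfrsf4, the receptor OX40 of the IL-2 and STAT5 and co-stimulatory lists, was among the top 10 genes of a Tconv sub-cluster of the CD4 libraries. That sub-cluster made up 28.8% of Tconv in Lag3KO_CD4 1, 3.71% in Lag3KO_CD4 2, 11.2% in WT_CD4 1 and 4.24% in WT_CD4 2. Its part in the called lists was not tested. Adjusted over the list alone, Tnfrsf18 (0.43 ± 0.13), the receptor GITR, Ctla4 (0.65 ± 0.19), an inhibitory receptor, and Il2rb (0.34 ± 0.11), an IL-2 receptor chain, were higher in the IL-2 and STAT5 list, and Jun (-0.69 ± 0.17), an immediate early transcription factor of a list that was not called, was lower. Without Lag3KO_CD4 1, the library labelled WT_CD45 2 or WT_CD4 2 there were 1, 2 or 3 called lists.

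The genotype effect differed between Tregs and Tconv of the same libraries for 4 of 8985 genes in edgeR. Ccl5 was higher in Tregs relative to Tconv (difference of differences 0.96 ± 0.10 SE, adjusted p = 1.7e-14) and Tnfrsf4, the co-stimulatory receptor OX40, lower (-0.49 ± 0.11, adjusted p = 0.00682). A haemoglobin gene and a gene known by its clone name made up the rest. In the CD4 libraries, the Tconv sub-cluster with Tnfrsf4 among its top 10 genes ranged from 3.71% of Tconv (Lag3KO_CD4 2) to 28.8% (Lag3KO_CD4 1). Its part in the Tnfrsf4 difference was not tested. DESeq2 called 1 gene and the stricter Treg score 0 in edgeR. The count was 2 without Lag3KO_CD4 2 and 7 without the library labelled WT_CD45 2.

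The remaining comparisons used the CD45 libraries alone, 1 Lag3KO library against WT_CD45 1 and the library labelled WT_CD45 2, so the spread behind each SE and p comes from these 2 libraries alone and nothing can be said of the spread between Lag3KO mice. Monocytes or macrophages were the largest class, at 37.6% of cells in WT_CD45 1, 33.7% in the library labelled WT_CD45 2 and 34.0% in Lag3KO_CD45 1. Dendritic cells of the cDC2 or monocyte-derived kind made up 8.73%, 8.24% and 7.75%, plasmacytoid dendritic cells 2.68%, 2.78% and 3.12%, and B cells 1.71%, 2.46% and 2.76%. Microglia made up 0.746% (95% Clopper-Pearson interval 0.435 to 1.19), 1.23% (0.811 to 1.78) and 3.08% (2.44 to 3.84). Barcodes with both T cell and myeloid transcripts, which were set apart, made up 25.1%, 23.2% and 27.7%. In edgeR, 0 genes were called in monocytes or macrophages (392 at an unadjusted p under 0.05, DESeq2 0, but 84 with no filter) and 0 in B cells (125 at an unadjusted p under 0.05, DESeq2 0, 1 with no filter); each had 1 with mixed barcodes removed before clustering. Counts were 14 in CD8 T cells, 19 in cDC1, 33 in NK cells, 67 in migratory dendritic cells, 70 in plasmacytoid dendritic cells and 80 in cDC2 or monocyte-derived dendritic cells. With mixed barcodes removed before clustering the counts were 31 in cDC1, 11 in NK cells, 49 in migratory, 42 in plasmacytoid and 14 in cDC2 or monocyte-derived dendritic cells. With no filter they were 16, 20, 16, 45, 0 and 107 from CD8 T cells on, so 0 calls were left in plasmacytoid dendritic cells (511 at an unadjusted p under 0.05). DESeq2 called 0, 0, 4, 6, 6 and 0 in the same order, with 9 (CD8), 24 (cDC1) and 64 (cDC2) at an unadjusted p under 0.05 where it called 0.

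The type I interferon response list was called lower in Lag3KO_CD45 1 than in the 2 libraries labelled WT in 6 of the 8 classes by camera with its preset correlation, and in 0 with an estimated one. In monocytes or macrophages 32 of 34 were negative (median -0.35, camera adjusted p = 1.0e-07, adjusted p = 0.993 with an estimated correlation), with Ifit2 (-1.13 ± 0.20 SE), Oasl1 (-0.93 ± 0.17), Rsad2 (-0.84 ± 0.17) and Isg15 (-0.56 ± 0.14) among the 5 lower adjusted over the list alone, and 0 over all genes in edgeR. The list was also called lower in CD8 T cells (12 of 13 negative, 2.4e-04), NK cells (13 of 14, 2.8e-04), plasmacytoid dendritic cells (19 of 23, 2.3e-04), migratory dendritic cells (24 of 30, 0.00208) and B cells (9 of 10, 0.00486; adjusted p = 0.968, 0.966, 0.506, 0.691 and 0.832 with an estimated correlation, in that order). In B cells the dissociation list (14 of 15 negative, camera adjusted p = 0.00486), the heat shock list (17 of 19 negative, 0.00486) and mitochondrially encoded genes (11 of 11 negative, 0.0172) were called lower with it, and in plasmacytoid dendritic cells the dissociation list (13 of 18 negative, 0.0139; adjusted p = 0.832 in B cells and 0.506 in plasmacytoid dendritic cells with an estimated correlation). Isg15 differed by -1.89 ± 0.57 in CD8 T cells and -1.72 ± 0.50 in NK cells.

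**Figure D4:**
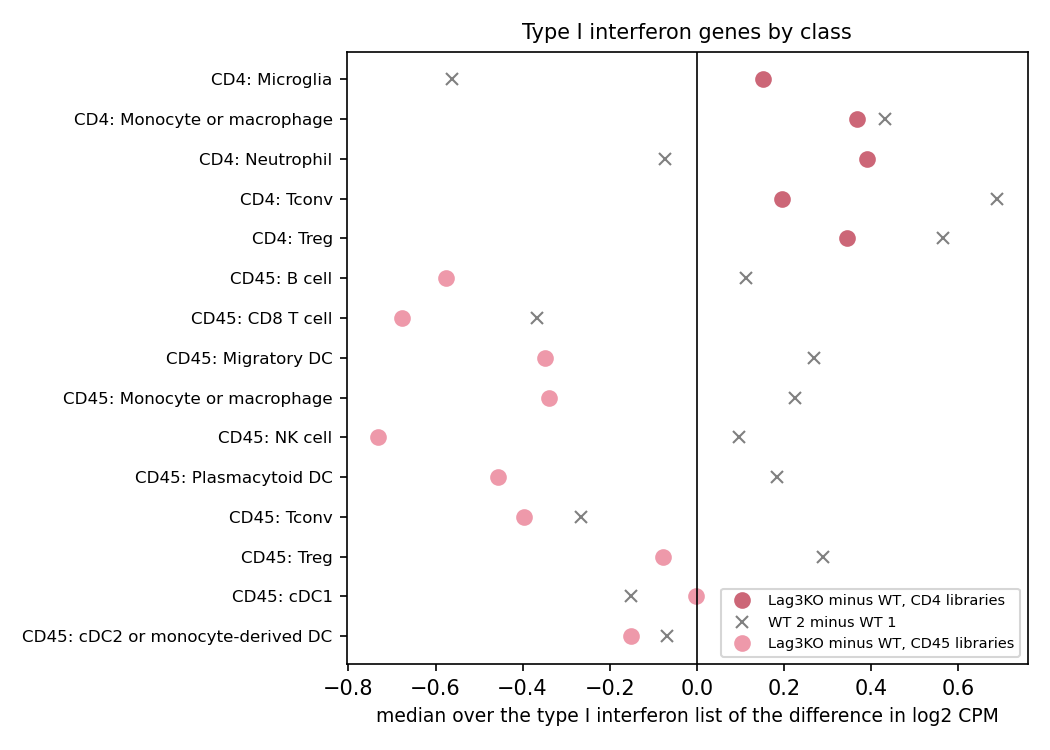
Median over the type I interferon list of the log2 CPM difference, Lag3KO minus WT (circles, coloured by sort), and WT 2 minus WT 1 (crosses), for each class and sort with enough cells. The Lag3KO minus WT medians were negative in 10 of 10 classes of the CD45 libraries, where WT 2 is the library labelled WT_CD45 2, and positive in 5 of 5 of the CD4 libraries; in 6 of 15 pairs the WT libraries differed by as much.

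CD8 T cells of Lag3KO_CD45 1 had more transcripts of the cytotoxic granule proteases Gzma (0.86 ± 0.18 SE, adjusted p = 0.00110) and Gzmb (0.99 ± 0.25, adjusted p = 0.0134) and of Lgals1, galectin-1 (0.62 ± 0.17, adjusted p = 0.0306; edgeR). Gzma was 3708 CPM there, against 2051 in WT_CD45 1 and 2035 in the library labelled WT_CD45 2. Klra7, an NK receptor gene, had 0 UMIs against 51, at least 5.56-fold lower. Whether Klra7 follows a chromosome segment carried with the Lag3 allele was not tested. NK cells of Lag3KO_CD45 1 (24 cells) had less Cd74 (-2.42 ± 0.20), H2-Aa (-2.74 ± 0.32), H2-Eb1 (-3.30 ± 0.38) and H2-Ab1 (-2.53 ± 0.31), all of MHC class II presentation, and more Arg1 (4.52 ± 0.53), S100a8 (3.40 ± 0.40) and Fth1 (1.17 ± 0.14), markers of macrophages, neutrophils and iron storage. Cd74, the H2 genes and Arg1 belong to the myeloid marker list, a check for RNA of other cells. Mixed barcodes were 24.6% of the NK cluster before they were set apart. Whether these transcripts come from the NK cells themselves was not tested.

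Among dendritic cells, the migratory class of Lag3KO_CD45 1 had more Apoe (2.04 ± 0.13 SE), a lipid carrier, Lyz2 (1.38 ± 0.13), lysozyme, and C1qb (1.49 ± 0.17). A cluster with C1qb among its top 10 genes made up 21.1% of this class in Lag3KO_CD45 1. It made up 6.48% in WT_CD45 1 and 7.58% in the library labelled WT_CD45 2. Before mixed barcodes were set apart, they were 72.3% of that cluster. Whether this mix of clusters sets the differences of the migratory class was not tested. All 19 complement and phagocytosis genes were positive (camera adjusted p = 3.2e-10, adjusted p = 0.657 with an estimated correlation), 5 of them past the threshold over all genes and 12 adjusted over the list alone. Microglia markers (5 of 5 positive, camera adjusted p = 0.00646) and homeostatic microglia genes (8 of 9 positive, 0.00208) were called higher there too, with 0 members past the threshold over all genes (adjusted p = 0.657 with an estimated correlation for each), in the library where the share of microglia was 3.08%. The plasmacytoid class had less Apoe (-2.44 ± 0.18), Ifitm3 (-2.41 ± 0.27) and Ccl5 (-1.57 ± 0.20). There 16 of 17 complement and phagocytosis genes and 10 of 11 chemokines were negative (camera adjusted p = 1.4e-09 for each, adjusted p = 0.506 with an estimated correlation for each), with Cxcl2 (-4.07 ± 0.53, 3 UMIs against 102) the lowest chemokine. Myeloid markers moved with these genes, up in the migratory class (16 of 24 positive, camera adjusted p = 2.1e-04, 0.657 with an estimated correlation) and down in the plasmacytoid class (20 of 23 negative, camera adjusted p = 3.0e-07, 0.506 with an estimated correlation). In cDC1, Ccl17 (1.83 ± 0.24), a chemokine of dendritic cells, and C1qc (1.00 ± 0.22) were higher and the chaperone Hspa8 (-0.87 ± 0.16) lower. In cDC2 or monocyte-derived dendritic cells Cd8a (2.81 ± 0.36) and Siglech (2.10 ± 0.30), markers of CD8 T cells and of plasmacytoid dendritic cells, and Chil3 (1.98 ± 0.27), a monocyte lectin, were higher. The mix of clusters in this class differed too. A cluster with Cd209a and Cd7 among its top 10 genes made up 41.4% of it in Lag3KO_CD45 1. That share was 23.1% in WT_CD45 1 and 20.4% in the library labelled WT_CD45 2, and its part in these differences was not tested. Tmsb10, an actin-binding thymosin, was lower in 6 of 8 classes in edgeR, and negative in 8 of 8 (median -0.76). It was 1 of 13 genes lower in at least 3 classes, while 0 were higher in as many; the classes come from the same 3 libraries, so a shift of a whole library recurs in each. Others of the 13, named after their values were seen, were the ribosomal genes Rps27rt (6 classes, median -0.83), Rps7 (5, -0.66) and Fau (3, -1.08) and the nuclear RNA Malat1 (3, -0.38). Leaving out a library in these classes leaves 1 against 1, which has no replicate.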

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

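All tests in this part were chosen after the result was seen, except those of the called lists over splits of the libraries.

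In the CD4 libraries, genotype differences of T cells gathered near Lag3 and on Tpm3. Genes within 20 Mb of Lag3 passed p under 0.01 more often than other genes. That held in Tregs (odds ratio 5.28, two-sided Fisher's exact p = 0.00376) and in Tconv (10.3, exact p = 6.1e-05). It fits a chromosome 6 segment carried with the Lag3 allele, which Emp1 and Clec2i may follow. Of the 5 near genes under 0.01 in Tregs 3 were called genes, and of the 6 in Tconv 2 were. The test thus partly counts the calls that prompted it, and the classes come from the same libraries. The odds ratio was 5.34 in monocytes or macrophages of the CD4 libraries (exact p = 0.00984), 2.07 in microglia (0.145) and 0 in neutrophils (1, 0 of 26 near genes), and 0.669 to 2.59 in 5 classes of the CD45 libraries with the library labelled WT_CD45 2 (exact p 0.0848 to 1), so it passed in 3 of 5 classes of the CD4 libraries and 0 of 5 of the CD45 libraries. The sum of Tpm3 and Tpm3-rs7 in Tregs was 0.991 of the WT level, which fits reads shared between the copies. Tpm3-rs7 made up 1.53% and 2.03% of both genes' UMIs in WT_CD4 1 and 2 and 81.2% and 80.4% in Lag3KO_CD4 1 and 2, but 44.2% in WT_CD45 1, 4.97% in the library labelled WT_CD45 2 and 36.6% in Lag3KO_CD45 1, which argues against LAG3 loss alone setting Tpm3.

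Lag3 and Foxp3 tags part the libraries differently from the genotype labels. Lag3KO_CD45 1 held Lag3 at 0.106 CPM, which argues against a swap with the library labelled WT_CD45 2. Foxp3 stood at 215.8 CPM in the Tregs of the library labelled WT_CD45 2, above those of the Lag3KO libraries (4.6 to 10.9). It was as low in WT_CD4 1 and 2 (12.4 and 9.36), so Foxp3 cannot tell a Lag3-deficient library from a WT one. A Lag3-deficient library under a WT label therefore stays open. In the 5 libraries with little Foxp3, pooled, 6 Treg markers that did not name the class were compared between Tregs and Tconv. Their Treg to Tconv ratios had lower 95% counting bounds of 1.19 to 12.4. For 6 of 6 the bound lay above the ratio of a class with Tregs diluted as far as Foxp3 (1.04 to 3.22). This argues against other T cells as the whole source of the low Foxp3 in the pool, but a lesser dilution stays open. In the WT_CD45 libraries the ratio was higher for Ebi3 (19.6 against 4.98), Lrrc32 (34.7 against 17.4), Itgae (13.8 against 7.67) and Entpd1 (2.00 against 1.65). It was lower there for Nt5e (1.84 against 2.06) and Socs2 (1.56 against 1.84). Entpd1 stood at 1.02 in its lowest library, below its diluted ratio of 1.07. An allele or reporter that alters the 3′ ends of Lag3 and Foxp3 could also be involved and was not tested.

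The type I interferon list of monocytes or macrophages was called higher in Lag3KO in the CD4 libraries and lower in the CD45 libraries, where the WT group holds the library labelled WT_CD45 2 (limma camera, unadjusted p = 2.3e-15 for the difference). With an estimated correlation that p is 0.0753, so a single effect of genotype in both sorts stays undecided. The call within each sort was lost with an estimated correlation as well. In 6 of 15 class and sort pairs the WT libraries differed by as much as the genotypes, 4 of 5 in the CD4 sort and 2 of 10 in the CD45 sort, which leaves differences between single libraries undecided too. In Tconv, Tregs and monocytes or macrophages of the CD4 sort the list was higher in library 2 than in library 1 of WT (0.69, 0.56 and 0.43) and of Lag3KO (0.82, 0.64 and 0.21), and haemoglobin parts these libraries in the same way. In microglia and neutrophils it was lower in library 2 of WT (-0.56 and -0.074) and not in library 2 of Lag3KO (0.0094 and 0.24). Libraries of the same number are not matched by their labels, since the numbers are accession order. Set side by side by number, Lag3KO minus WT was positive for both numbers in Tregs (0.28 and 0.38) and Tconv (0.12 and 0.21). So it was in monocytes or macrophages (0.63 and 0.26) and neutrophils (0.54 and 0.64), but not in microglia (-0.0266 and 0.48). These 2 unmatched comparisons cannot decide whether genotype or single libraries set the list.

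The Treg genotype effect in the CD4 libraries minus that in the CD45 libraries was -2.27 for Tpm3 and 3.55 for H2-Aa, the latter resting on the library labelled WT_CD45 2 as well. In the CD4 libraries, genotype changed 29 genes in microglia, 10 in monocytes or macrophages and 3 in neutrophils (edgeR). Haemoglobin reached 13123.4 CPM in WT_CD4 2 and 3189.9 CPM in Lag3KO_CD4 2, and 0 in the other CD4 libraries.

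All 34 splits of the 7 libraries into 3 and 4 that the model can fit, the real one among them, were compared for 5 counts, and chance can be excluded for none of them. The count of 0 Tconv genes is reached by all 34 splits whatever their values (highest other 61), so it tests nothing. At least the real 8 Treg genes came up in 5 splits (highest other 11) and at least the real 4 genes of Treg minus Tconv in 22 (highest other 15). At least the real 1 called Treg list came up in 28 (highest other 10) and at least the real 7 called Tconv lists in 21 (highest other 16). The Tconv splits with 61 and 51 genes set WT_CD4 2 and Lag3KO_CD4 2, which hold haemoglobin, apart from WT_CD4 1 and Lag3KO_CD4 1, which points to a structure of the samples. The 4 other splits that do so gave 11, 4, 0 and 0 genes, so this pairing alone does not set the count. With haemoglobin as a block the genotype gives 11 genes.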

How the results depend on the processing

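The alternatives were planned, except the haemoglobin block, mixed barcodes removed before clustering, the Treg score of at least 1.0, the share within a single sort, those of the difference between sorts, T cell resolution 2.0 for lists, other list tests in the CD45 classes, class shares at other T cell resolutions, and all of the CD4-library classes, which were added after the data were seen. The score of at least 1.0 was the naming rule planned first, and it was run as an alternative only after the rule had been changed. No paired analysis was possible because the labels share no replicate numbers. The numbers are accession order. The haemoglobin block groups libraries by a feature of the data, not by their labels. Treg genes and lists were not tested in cells with a Foxp3 UMI, since each CD4 library has fewer than 20; the Treg share was. The cause of each change was not tested. Directions that involve the CD45 libraries include the library labelled WT_CD45 2.

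Of the Treg results over both sorts, the 8 genes became 14 with doublets kept, 2 with a Treg score of at least 1.0, 20 with no filter and 5 in DESeq2. The 9 genes of the CD4 libraries became 15 with mitochondrial UMIs of at most 5%, 22 with doublets kept, 5 at T cell resolution 2.0, 3 with a score of at least 1.0, 23 with no filter and 22 with the haemoglobin block. The 1 gene of the CD45 libraries became 3 with mitochondrial UMIs of at most 5%, 7 with doublets kept, 2 at T cell resolution 0.5, 3 at 2.0, 2 with mixed barcodes removed first, 2 with RLE, 7 with no filter, 0 in DESeq2, 8 with only the libraries of this sort and 6 with the haemoglobin block. The difference between sorts went from 2 genes to 11 with doublets kept, 4 with mixed barcodes removed first, 1 with a score of at least 1.0 and 7 with no filter. Leaving out 1 library gave 0 to 14 genes over both sorts, 3 to 17 in the CD4 libraries, 1 to 6 in the CD45 libraries and 2 to 7 for the difference.

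In Tconv, the 0 genes over both sorts became 3 without cells that hold a Foxp3 UMI, 1 with a Treg score of at least 1.0, 27 with no filter, 1 in DESeq2 and 11 with the haemoglobin block. The 4 genes of the CD4 libraries became 25 with no filter and 10 with the block, the 0 of the CD45 libraries 12 with no filter and 28 with only the libraries of this sort, and the 0 of the difference 1 by Foxp3 UMI, 12 with no filter and 1 in DESeq2. Treg minus Tconv went from 4 genes to 1 with doublets kept, 1 at T cell resolution 2.0, 0 with a score of at least 1.0 and 1 in DESeq2. Leaving out 1 library gave 0 to 8 genes over both sorts, 2 to 9 in the CD4 libraries, 0 to 1 in the CD45 libraries, 0 to 2 for the difference and 2 to 7 for Treg minus Tconv.

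In the CD45 classes, DESeq2 took CD8 T cells from 14 to 0, cDC1 from 19 to 0, cDC2 or monocyte-derived dendritic cells from 80 to 0, migratory dendritic cells from 67 to 6, NK cells from 33 to 4 and plasmacytoid dendritic cells from 70 to 6. No filter gave 1 in B cells, 84 in monocytes or macrophages, 16 in NK cells and 0 in plasmacytoid dendritic cells. With mixed barcodes removed first there were 1 in B cells, 31 in cDC1, 14 in cDC2 or monocyte-derived dendritic cells, 1 in monocytes or macrophages, 11 in NK cells and 42 in plasmacytoid dendritic cells. In the CD4 libraries, no filter and DESeq2 gave 18 and 6 in microglia, 17 and 5 in monocytes or macrophages and 39 and 5 in neutrophils, and leaving out 1 library gave 7 to 45, 13 to 33 and 12 to 45.

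The Treg share difference reversed to 2.97 points in the CD45 libraries alone, and leaving out 1 library gave -6.33 to -0.233. From -2.61 it went to -1.40 with a Treg score of at least 1.0, -1.62 with mitochondrial UMIs of at most 5% and -3.47 by Foxp3 UMI. The CD8 T cell share of Lag3KO_CD45 1 went from 1.30% to 0.855% with mitochondrial UMIs of at most 5% and 0.834% with doublets kept. That of WT_CD45 1 went from 1.32% to 0.749% and 0.732%, and that of the library labelled WT_CD45 2 from 2.82% to 2.10% and 1.92%. In the order just given, T cell resolution 0.5 gave 0.933%, 0.921% and 2.14%, T cell resolution 2.0 gave 0.811%, 0.834% and 2.09%, and resolution 2.0 over all cells 0.973%, 0.921% and 2.18%. With mixed barcodes removed first those of the 2 libraries labelled WT became 0.746% and 1.91%, and the Tconv share of WT_CD45 1 became 4.91%.

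The 1 called Treg list became 0 with an estimated correlation, 0 in fry and 3 at T cell resolution 2.0, and the 7 called Tconv lists became 0, 0 and 4 by Foxp3 UMI. Leaving out 1 library gave 0 to 6 and 1 to 9. With an estimated correlation there were 0 called lists in B cells (from 4), CD8 T cells (1), cDC1 (3), cDC2 or monocyte-derived dendritic cells (1), migratory dendritic cells (7), monocytes or macrophages (2), NK cells (1) and plasmacytoid dendritic cells (13), and in the microglia (6), monocytes or macrophages (4) and neutrophils (4) of the CD4 libraries. In fry there were 0 in each of these but cDC2 or monocyte-derived dendritic cells.

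Some uncalled Treg genes reversed: Il10 to -0.0310 at T cell resolution 2.0 and -0.18 with a Treg score of at least 1.0, Ifng to 0.15 with mitochondrial UMIs of at most 5% and 0.36 with doublets kept, and Csf2 to 0.28 with mitochondrial UMIs of at most 5%, 0.11 in DESeq2 and 0.0281 with the haemoglobin block. Ifitm3 reversed to -0.31 with a score of at least 1.0. When 1 library was left out, values in Tregs ran from -1.21 to 0.0488 for Il17a, -0.20 to 1.13 for Il10, -0.28 to 0.45 for Il2ra, -1.20 to 0.47 for Ifng and -0.0380 to 0.55 for Myc, each with both signs. In Tconv they ran from -0.88 to 0.38 for Il17a, -0.64 to 0.61 for Ifng and -0.16 to 1.72 for Csf2.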

Other observations

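The tests of this part were chosen after the result was seen.

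In microglia of the CD4 libraries, 4 of 16 genes of resting microglia were lower in Lag3KO over all genes. Gpr34 fell by 1.28 ± 0.26 (SE; log2 -1.28), P2ry12, a purine receptor of resting microglia, by 1.00 ± 0.19, Siglech by 0.85 ± 0.22 (-0.85) and Fcrls, a microglial Fc receptor-like gene, by 3.86 ± 0.30 (-3.86), while Ccl2, a chemokine for monocytes, rose by 1.05 ± 0.19 (edgeR). All 16 homeostatic microglia genes were negative (camera adjusted p = 1.7e-07, 0.590 with an estimated correlation), 8 of them past the threshold adjusted over the list alone and 12 not past it over all genes. Fcrls lies on chromosome 3 as Tpm3 does, and a segment carried there was not tested. The immediate early and dissociation list was called lower too (15 of 19 negative, camera adjusted p = 0.0394, 0.884 with an estimated correlation), and microglia made up 59 of 1883 and 46 of 1362 cells in WT_CD4 1 and 2 and 109 of 1443 and 98 of 1781 in Lag3KO_CD4 1 and 2. Without Lag3KO_CD4 1 the 29 changed genes became 7, without WT_CD4 2 they became 12 and without WT_CD4 1 they became 45; DESeq2 called 6.

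Monocytes or macrophages of the CD4 libraries had more Ccl7, a monocyte chemokine (2.83 ± 0.37 SE), and S100a8 (2.41 ± 0.39) in Lag3KO, and all 29 type I interferon genes were positive (camera adjusted p = 8.4e-07, 0.826 with an estimated correlation), with Isg15 (0.98 ± 0.24) and Ifit3 (1.28 ± 0.34) among 5 passing over the list alone and 0 over all genes. In neutrophils 16 of 17 interferon gamma genes were positive (camera adjusted p = 1.2e-07, 0.332 with an estimated correlation), with Cxcl10 (2.52 ± 0.39) past the threshold over all genes. The 10 monocyte or macrophage genes became 33 without WT_CD4 1, 30 without WT_CD4 2 and 13 to 15 without a Lag3KO library, and the 3 neutrophil genes became 12 to 45.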
